A study of Homo sapiens with 6 samples.

How the data were processed

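RNA of 6 libraries from PR-infected human umbilical vein endothelial cells was sequenced, 1 library per group as given in the labels. Per the submitters' processing notes, 50-base reads were aligned to hg19 with TopHat2 2.0.4, and transcripts were assembled and quantified with Cufflinks 2.0.1, with Cuffdiff also named. Each deposited file holds the assembly of 1 library by itself. Per the file headers and attribute names, the authors give each assembled transcript a value in FPKM (fragments scaled to effective transcript length and to all mapped fragments), its interval, isoform fraction and read depth. Transcripts carry no gene names. Cufflinks intervals were used to choose named genes and, among these, genes whose difference with progesterone changed direction. The ratio of read depth to FPKM gave the mapped fragments behind each file, 40377788 in PR, 33480977 in PR + P, 36219851 and 33703954 at 4 h of LPS without and with progesterone, and 38121814 and 37568488 at 8 h. Fragment numbers were also computed from the Cufflinks intervals alone, on genes with 1 transcript and under 200 fragments. Of these, 80.2% to 81.3% lay within 0.02 of a whole number. The mapped fragments did not enter that check, so it does not bear on them. The file of LPS alone at 4 h stops within chromosome 5 and lists nothing of chromosomes 6 to 9 and X. Genes beyond its end were compared without it. Chromosome Y and XIST were left out.

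Gene names were assigned by structure, since no gene annotation of hg19 was used here. This route was chosen after the files were seen and goes beyond the naming rule fixed before the data were examined. Each transcript of at least 3 exons was broken into units of 2 introns and the exon between them, and the chromosome, strand and 3 lengths of each unit were matched to GENCODE release 29. That release is on GRCh38, so lengths and no coordinates were compared, and all printed coordinates are those of the deposited hg19 files. Of 584113 units 556178 matched (95.2%), and 102024 of 106093 transcripts were named (96.2%), with 353 matching several genes. Decoys with introns shifted by 3 bases gave 34 matches, and decoys on the other strand 40. This named 10555 genes, 10310 of them protein coding. Genes with fewer exons are missing.

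The same gene was assembled into different numbers of transcripts and fragments in different libraries. The planned gene value, the sum of FPKM over transcripts, therefore moved with the assembly, and it was replaced after the files were seen and before any limma result. The value used weights each transcript's FPKM by its effective over full length and by its overlap with 1 exon model per gene, made of bases seen in at least 2 libraries. Effective length was taken as length minus 203.2 bases for longer transcripts. For short ones the shift was interpolated by length from the values that the Cufflinks intervals implied. A gene entered a comparison with FPKM of at least 1 in either library and at least 25% of its model assembled in both. Values resting for over 50% on transcripts with at least 20% of their length in another gene's model were left out. The assembly filter was set after a run without it and after its coverage of genes of interest was viewed, and the entry rule of 4 of 6 libraries for the fits was also set after the files were seen. The choice of LPS-induced genes did not require the gene to be assembled in PR.

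Pairs of libraries were compared by the difference in log2(FPKM + 1), with a 2-fold threshold for counts. Intervals of ratios are 95% and cover counting error only, for genes with at least 10 fragments in each library. limma 3.58.1 in R 4.3.3 fitted an additive model of background (no LPS, LPS at 4 h, LPS at 8 h) and progesterone to all 6 libraries, with 2 residual and 2.6 prior degrees of freedom, a trend in the prior variance, and Benjamini-Hochberg adjustment at 0.05. Genes needed FPKM of at least 1 in 2 libraries and assembly in 4 of 6. The 22 gene lists hold 380 distinct genes and were fixed before the data were examined. A list's median was set against 10000 random lists matched in 20 bins of expression. LPS-induced genes were at least 4-fold higher in LPS than in PR at one time and were measured at the other. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

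Named genes were the 8 highest and 8 lowest per pair with FPKM of at least 5 and separate Cufflinks intervals, up to 4 members per list, 17 genes fixed in advance, and the 10 of smallest adjusted p in each direction of each fit. Some genes that meet these rules are not reported here. List members given beyond these were chosen after their values were seen. The fit was tested on simulated data with known changes in 200 of 7759 genes, and 92.0% of 2-fold and 97.0% of 4-fold changes were recovered, with 11 unchanged genes called (5.5% of calls). The simulated libraries had independent noise and no LPS response, assembly effect or shift shared by the libraries with progesterone. The test therefore says nothing on errors from those sources. Of 100 random lists, 4 lay outside the central 95% of matched lists. Alternatives planned before the data were examined were a pseudocount of 0.1, no filter beyond FPKM above 0, median-ratio rescaling, the most abundant transcript in place of the gene value, a fit without a variance trend, leaving out each pair, a 2-fold choice of induced genes, and choosing them at the time of measurement. The planned rule for the most abundant transcript took the highest mean over 6 libraries, and since transcripts are not shared between files it was replaced by the highest in each library. Alternatives added after the data were seen were the planned sum, no assembly filter, a filter at 50%, fused transcripts kept, the analysis as first planned, and assembly in all 6 libraries.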

Results

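Primary human umbilical vein endothelial cells, which line the vein of the umbilical cord, were infected with a lentivirus that carried the human progesterone receptor (PR). RNA was sequenced from 6 groups with 1 library each. The cells were left untreated (PR), given progesterone (PR + P), given lipopolysaccharide (LPS, a bacterial outer membrane component that activates the receptor TLR4) for 4 h or 8 h, or given LPS and progesterone together for 4 h or 8 h. The labels gave 1 µM LPS and, for the libraries with both agents, 100 nM progesterone. The series asks which endothelial genes the ligand-bound receptor controls and how it changes cytokine production after LPS. PGR, which encodes the receptor (chromosome 11, 100909844 to 100999806, hg19), stood at 1008 FPKM in PR, 1031 in PR + P, 1363 and 1821 at 4 h without and with progesterone, and 1324 and 1749 at 8 h. Transcript of the introduced and of the resident gene was not told apart.

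The deposited values implied between 33480977 and 40377788 mapped fragments per library. The assemblies gave 10555 named genes. The file of the library with LPS alone at 4 h stops within chromosome 5 and holds nothing of chromosomes 6 to 9 and X. The 2232 genes beyond its end, IL6, TNFAIP3 and FKBP5 among them, were compared without that library. No group was replicated, so a difference between 2 libraries carries no p-value. Ratios of 2 libraries are given with 95% intervals that cover counting error only. Across libraries, progesterone and LPS were tested with limma on log2(FPKM + 1), with each pair of libraries as 1 replicate and 2 residual degrees of freedom. The labels do not say whether the libraries came from separate cultures. The p-values measure only the spread between these libraries, which may be technical. With 1 library per group, a progesterone difference that changes with background, or an LPS difference that changes with progesterone, counts as spread. A gene with such a difference may therefore not pass.

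LPS raised chemokines, genes of NF-kB feedback and some leukocyte adhesion molecules, SELE, VCAM1 and ICAM1 among them. SELE, the E-selectin that captures rolling leukocytes (chromosome 1, 169691797 to 169703211), stood at 0.63 FPKM in PR, 155 after 4 h and 94.3 after 8 h of LPS. ICAM1, a ligand of leukocyte integrins (chromosome 19, 10380654 to 10399172), stood at 12.3, 424 and 300 FPKM, and VCAM1, which binds the integrin VLA-4 (chromosome 1, 101185266 to 101205971), at 6.19, 118 and 84.6 FPKM. The monocyte attractant CCL2 (chromosome 17, 32581986 to 32584222) stood at 18.5, 371 and 312 FPKM. The neutrophil attractants were higher as well. CXCL8 (chromosome 4, 74606257 to 74610352) stood at 7.65, 125 and 112 FPKM, CXCL1 at 35.4, 556 and 395 FPKM, and CXCL6 at 1.22, 39.3 and 64.7 FPKM. The growth factors CSF2 and CSF3, which drive granulocyte and macrophage output, were listed at 0 in PR and at 8.84 and 23.1 FPKM after 4 h. CCL20, CX3CL1 and CXCL10 were also listed at 0 in PR and stood at 48.6, 11.7 and 6.92 FPKM after 4 h. The bar plot of these genes sets the 6 libraries side by side.

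**Figure D1:**
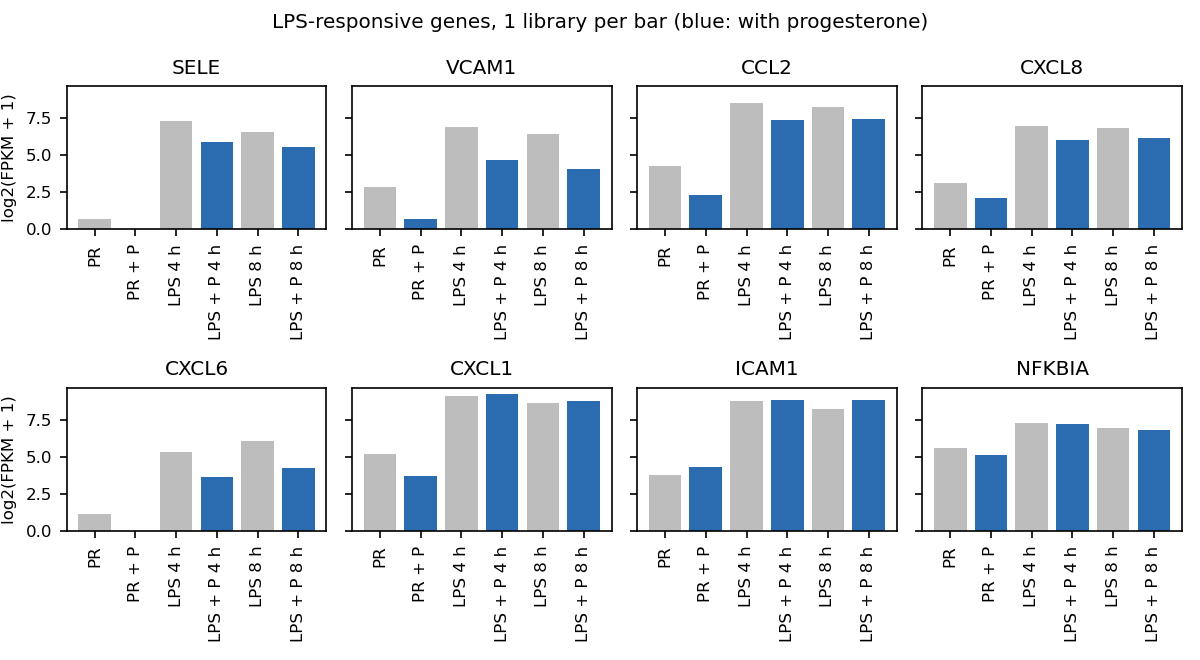
Level of 8 LPS-responsive genes in each of the 6 libraries, as log2(FPKM + 1), with 1 library per bar, grey without and blue with progesterone. VCAM1 stood at 118 FPKM at 4 h of LPS and at 24.7 with progesterone added, while ICAM1 stood at 424 and 453 FPKM.

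In the limma fit over all 6 libraries, 49 of 7759 genes rose and 5 fell with 4 h of LPS, and 48 rose and 3 fell with 8 h, after Benjamini-Hochberg adjustment. At an unadjusted p under 0.05 the counts were 1427 and 1215 genes. VCAM1 rose by 4.02 on the log2 scale at 4 h (SE 0.09, limma adjusted p = 0.0018) and by 3.47 at 8 h (SE 0.09, limma adjusted p = 0.0026). The rise of SELE was 6.23 and 5.72 (SE 0.18 at each time) and that of ICAM1 4.77 and 4.51 (SE 0.14), with limma adjusted p from 0.0023 to 0.0026. CXCL8 rose by 3.9 and 3.91, CXCL6 by 3.91 and 4.58, and CCL2 by 4.64 and 4.54. SELE and CXCL6 were listed at 0 in PR + P and ELOVL7 in PR, and VCAM1 stood at 0.6 FPKM and RND1 at 0.2 FPKM in PR + P. The fitted sizes of these genes depend on the added constant. Among the other leading genes were RND1, a small GTPase (2.66 and 2.24), ICOSLG, a ligand that costimulates T cells (1.98 and 1.84), ELOVL7, a fatty acid elongase (2.43 and 3.06), and RELB, a subunit of NF-kB (2.21 and 1.99). Of the 5 genes that fell at 4 h, CALCRL, a subunit of the adrenomedullin receptor, fell by 0.92 (SE 0.08), the growth factor BMP4 fell by 1.05 (SE 0.11) and PRICKLE1, of planar cell polarity, fell by 0.94 (SE 0.09), each lower in both pairs. PRICKLE1 had a limma adjusted p of 0.052 without the 8 h pair, and BMP4 of 0.071 and CALCRL of 0.058 in a fit without a trend in the prior variance. The remaining 2, TYSND1 and CCDC188, and at 8 h ZNF688 and MRPL49, were at or near 0 in both libraries of that time, and TBC1D8 fell by 1.69 at 8 h. SNF8, an endosomal sorting subunit, rose by 1.55 at 8 h.

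The fixed lists moved apart under LPS. Of 19 tested cytokines and chemokines, 9 rose at 4 h and 10 at 8 h over all genes, and 18 rose at each time when adjusted over the list alone. Of 15 NF-kB feedback and survival genes, 9 and 7 rose, and all 15 at each time adjusted over the list alone. They included the inhibitor NFKBIA (47.0 FPKM in PR, 157 at 4 h and 122 at 8 h), NFKB2, TNFAIP2 (5.71, 173 and 104 FPKM) and the ribonuclease gene ZC3H12A (2.99, 23.1 and 14.7 FPKM). Of 12 adhesion molecules, SELE, VCAM1 and ICAM1 rose at 4 h, and JAM2 with them at 8 h (4 and 7 adjusted over the list alone). Single genes rose in other lists, PLAU (urokinase) at 4 h, MMP10 (stromelysin) at 8 h and GCH1, which makes a cofactor of nitric oxide synthase, at both times. No TLR4 pathway component, junction, identity, Notch, cholesterol synthesis, cell cycle or unfolded protein response gene passed at either time over all genes. Adjusted over the list alone, 1 TLR4 component rose at each time, and of 4 Notch genes 2 fell at 4 h and 3 at 8 h while 1 rose. None of the 18 interferon-stimulated genes passed over all genes, while 3 rose and 1 fell at 4 h, and 4 rose and 1 fell at 8 h, adjusted over the list alone. In the pair at 8 h, the RNA sensor IFIH1 was higher with LPS (3.45 and 9.64 FPKM), and the list's median log2 difference of 0.48 lay at percentile 100.0 of 10000 matched random lists. Antigen presentation genes were higher in 14 of 15 members in that pair, with TAP1, a peptide transporter, at 7.38 and 24.6 FPKM. None of the 6 tested passed at either time over all genes (3 rose at 8 h adjusted over the list alone), and TAP1 had a limma adjusted p of 0.317 over the pairs without LPS and at 8 h. Without the 8 h pair 5 cytokines rose at 4 h, and without the 4 h pair 5 rose at 8 h with 2 adhesion molecules and no matrix protease. For the genes beyond the end of the 4 h file, the limma fit over the pairs without LPS and at 8 h gave IL6 a rise of 2.05 (SE 0.14, adjusted p = 0.0418) and TNFAIP3, an NF-kB inhibitor, a rise of 2.08 (SE 0.1, adjusted p = 0.0233).

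Between 2 single libraries, 107 of 7692 genes were at least 2-fold higher and 33 lower at 4 h than in PR, and 129 and 46 of 9763 at 8 h. TNFAIP2 (ratio 30.3, 95% interval 28.6 to 32.2) was among the largest at 4 h. The lowest genes of rank at 4 h were RPL9, NPIPB14P, DHRS4, UFD1, SRRM2, COX20, MRPS18C and RPL29. RPL9, UFD1, SRRM2 and COX20 stood at 0.403, 7.75, 14.1 and 2.09 FPKM there and at 45.1, 35.3, 74.2 and 10.5 FPKM in the library with LPS and progesterone. The lowest at 8 h were ZNF511, AHNAK2, SDHAP2, AQP1, RPL6, NPIPB14P, SNRPE and SNHG5, while NOS3, the endothelial nitric oxide synthase, stood at 14.3 FPKM in PR and 5.80 at 8 h. The LPS calls of the fits over all genes rest on the length-weighted gene value. The planned sum over transcripts and the most abundant transcript each gave 0 genes at both times (limma, 497 and 427 genes at an unadjusted p under 0.05 for the sum). Over the 593 genes with 1 transcript in each library, both gave 4 genes at 4 h and 4 at 8 h. The length-weighted value gave 16 and 9 there. Over the 694 genes with equal transcript numbers, both gave 3 and 3, against 17 and 9. Without the 4 h pair, 32 genes passed at 8 h, and MRPS18C, AQP1, SNHG5, PRICKLE1, RND1 and TBC1D8 changed sign with the sum or the most abundant transcript.

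Without LPS, transcripts of several lists were lower with progesterone in these PR-infected cells, among them inflammatory, steroid-response, Notch, vasoactive and endothelial identity genes. VCAM1 stood at 6.19 FPKM in PR and 0.602 in PR + P (ratio 0.097, 95% interval 0.078 to 0.12). CCL2 stood at 18.5 and 4.06 FPKM, CXCL1 at 35.4 and 11.8 FPKM, CXCL8 at 7.65 and 3.24 FPKM and IL6 at 6.53 and 2.93 FPKM. ADAMTS1, a matrix protease (55.5 and 16.6 FPKM), and ANKRD1, a stress-responsive ankyrin protein (314 and 97.0 FPKM), were also among the lowest, as were DHRS4, KPNA2P3, TCAF2 and RAMAC. The highest were TNFRSF10A, a death receptor (ratio 8.62, 95% interval 7.73 to 9.61), GFPT2 of the hexosamine pathway (1.76 and 14.5 FPKM), the keratin KRT8 (2.98 and 19.6 FPKM), TOR1B, FASTK, PBLD, SERINC5 (3.00 and 15.8 FPKM) and HMGB1. ICAM1 was higher in PR + P (12.3 and 18.4 FPKM).

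In this pair 127 of 9799 genes were at least 2-fold higher and 85 lower in PR + P. Cytokines and chemokines were lower in 12 of 14 measured members, with a median log2 difference of -0.44 at percentile 0.01 of matched random lists. Steroid receptor response genes were lower in 13 of 16 (median -0.34, percentile 0.01), among them ERRFI1, an inhibitor of the EGF receptor (81.9 and 25.4 FPKM), ANGPTL4, a lipoprotein lipase inhibitor (15.02 and 5.91 FPKM), the kinase gene SGK1 (66.0 and 31.0 FPKM) and FKBP5, a chaperone of steroid receptors (59.1 and 38.9 FPKM). TSC22D3, known to respond to glucocorticoids, stood at 17.4 and 16.1 FPKM. Immediate early genes were lower in 7 of 8 (median -0.49, percentile 0.02), with KLF2 at 12.0 and 5.83 FPKM. Vasoactive genes were lower in 8 of 9 (median -0.49), with EDN1, the precursor of endothelin, at 151 and 65.9 FPKM. The Cufflinks interval of EDN1 in PR ran from 0.0 to 424 FPKM and held that of PR + P (64.0 to 67.8). Notch pathway genes had the lowest median of the lists in this pair (-0.69, percentile 0.0, 5 of 7 lower), and endothelial identity genes were lower in 19 of 19 (median -0.23, percentile 1.03). With the planned sum, VCAM1, GFPT2, PBLD, SERINC5, TNFRSF10A and the median of interferon-stimulated genes changed sign in this pair, VCAM1 to 1.09 on the log2 scale. With the most abundant transcript HMGB1 and the median of vasoactive genes changed sign as well. Genes named only from a list were not checked for this, and genes less than 2-fold apart were not counted.

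**Figure D2:**
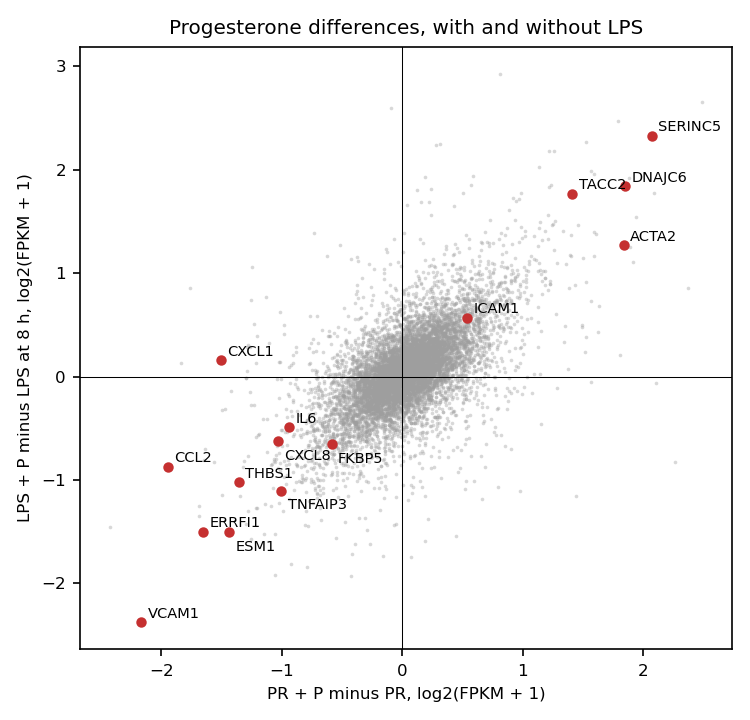
Log2 difference with progesterone in log2(FPKM + 1) without LPS (x axis) and at 8 h of LPS (y axis), with 1 grey point per gene and named genes in red. VCAM1 was low in both pairs (-2.17 and -2.37), while CXCL1 was lower without LPS (-1.51) and near its partner at 8 h (0.16).

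Under LPS, progesterone went with lower levels of most chemokines, E-selectin and VCAM1. ICAM1 and CXCL1 were not lower at either time, and NFKBIA was only slightly lower. VCAM1 stood at 118 FPKM with LPS alone and 24.7 with progesterone at 4 h (ratio 0.209, 95% interval 0.202 to 0.216), and at 84.6 and 15.6 FPKM at 8 h (ratio 0.184, 0.176 to 0.192). SELE stood at 155 and 58.0 FPKM at 4 h and at 94.3 and 46.4 FPKM at 8 h. CXCL10, an attractant of activated T cells, stood at 6.92 and 1.69 FPKM, then 10.3 and 1.33 FPKM. CCL20, which attracts dendritic cells, stood at 48.6 and 11.1 FPKM, then 34.4 and 8.91 FPKM. In contrast, ICAM1 stood at 424 and 453 FPKM at 4 h and at 300 and 446 FPKM at 8 h.

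Other chemokines lay lower too. CXCL6 stood at 39.3 and 11.5 FPKM at 4 h and 64.7 and 18.2 FPKM at 8 h, and CXCL5 at 14.9 and 3.62 FPKM and 18.4 and 5.29 FPKM. CCL2 had ratios of 0.443 (95% interval 0.43 to 0.457) and 0.546 (0.53 to 0.562), CXCL8 of 0.506 and 0.645, and CSF2 of 0.394 and 0.469. IL6, measured at 8 h, stood at 25.6 and 18.0 FPKM. CXCL1 stood at 556 and 593 FPKM at 4 h and at 395 and 443 FPKM at 8 h, and NFKBIA at 157 and 145 FPKM and at 122 and 111 FPKM. CXCL2 and CXCL3 are close paralogs whose reads were assembled partly together, and their values are not compared here. Of the feedback genes, TNFAIP3 had a ratio of 0.453 at 8 h (95% interval 0.436 to 0.472). IRAK2, a kinase of TLR signalling, stood at 22.6 and 8.84 FPKM at 4 h and at 16.0 and 6.53 FPKM at 8 h. PTGS2, the inducible cyclooxygenase, had ratios of 1.19 at 4 h (95% interval 1.08 to 1.32) and 1.05 at 8 h (0.955 to 1.15). NR4A1, an immediate early nuclear receptor, stood at 0.849 and 1.43 FPKM at 4 h and at 0.664 and 1.92 FPKM at 8 h.

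Cytokines and chemokines were lower in 17 of 19 measured members at 4 h (median -0.97, percentile 0.0 of 10000 random lists) and in 20 of 22 at 8 h (median -0.75, percentile 0.0). By at least 2-fold, 9 were lower at 4 h and 6 at 8 h, while 10 and 16 lay within 2-fold. Interferon-stimulated genes were lower in 15 of 17 and 17 of 19 members, with XAF1 at 5.21 and 1.22 FPKM and the antiviral MX1 at 8.58 and 3.60 FPKM at 8 h. NF-kB feedback genes had medians of -0.11 and 0.06, inside the range of random lists at both times. At 4 h RRAD, a small GTPase, stood at 1.39 and 67.7 FPKM, and at 8 h at 0.955 and 13.3 FPKM. ATF3, a stress-induced transcription factor, was higher at both times (4.98 and 21.0, then 3.93 and 8.07 FPKM), and FOS at 4 h (3.55 and 14.0 FPKM). KLF2, a flow-responsive transcription factor, was lower (10.4 and 3.26, then 10.3 and 2.22 FPKM). Cholesterol synthesis genes were higher in 8 of 14 at 4 h (median 0.29, percentile 99.99) and 14 of 19 at 8 h (median 0.23, percentile 99.03), with IDI1, an isomerase of the pathway, at 6.02 and 12.4 FPKM at 4 h.

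In all, 105 of 7639 genes were at least 2-fold higher and 76 lower at 4 h, and 192 and 120 of 9716 at 8 h. The rest of the highest were RPL9, SRRM2, UFD1, TXNL4B, COX20 and SLC26A11 at 4 h, and LYPLA1, GFPT2, ZNF155, SMCO4, SERINC5, PROX1 and an unnamed gene (ENSG00000285756) at 8 h. The rest of the lowest were ZNF765, ANKRD1, ATP5PB and HMGN2 at 4 h, and ATP5PB, AKTIP, NREP and GON4L at 8 h. With the sum or the most abundant transcript, AKTIP, GFPT2, GON4L, KLF2 and the medians of the antigen presentation, immediate early and Notch lists changed sign at 8 h. At 4 h those of the steroid response, vasoactive and Notch lists did.

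Taking the 3 pairs as replicates, progesterone lowered VCAM1, the gene with the smallest adjusted p, and 7 chemokines and cytokines. VCAM1 fell by 2.25 on the log2 scale (SE 0.07, limma adjusted p = 0.01), lower in 3 of 3 pairs. VCAM1 stood at 0.6 FPKM in PR + P, below the added constant of 1. Its fitted size, its SE and how close its pairs lay depend on that constant. ERRFI1 (chromosome 1, 8071782 to 8086365) fell by 1.56 (SE 0.06, limma adjusted p = 0.011). The endothelial proteoglycan ESM1 fell by 1.38 (SE 0.08), the matrix glycoprotein THBS1 by 1.17 (SE 0.08) and ANGPTL4 by 1.16 (SE 0.08), each with a limma adjusted p of 0.015. The remaining genes with the smallest adjusted p among those that fell were ARRDC2 (-1.18), TRIM16 (-1.08), the growth arrest gene GADD45A (-1.07), ICOSLG (-1.06) and BHLHE40, a clock-linked repressor (-0.97). Among those that rose were SERINC5 (2.0, SE 0.15), DNAJC6, a clathrin uncoating factor (1.8, SE 0.07), TACC2 (1.63), KLF5 (1.47), UBL3 (1.33), ATP6V0A1, of the proton pump (1.29), MTHFS (1.25), the thiamine transporter gene SLC19A2 (1.21) and USP12 (1.21). Each gene named here, though not the chemokines and cytokines as a group, passed the adjusted threshold in each fit that left out 1 pair.

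**Figure D3:**
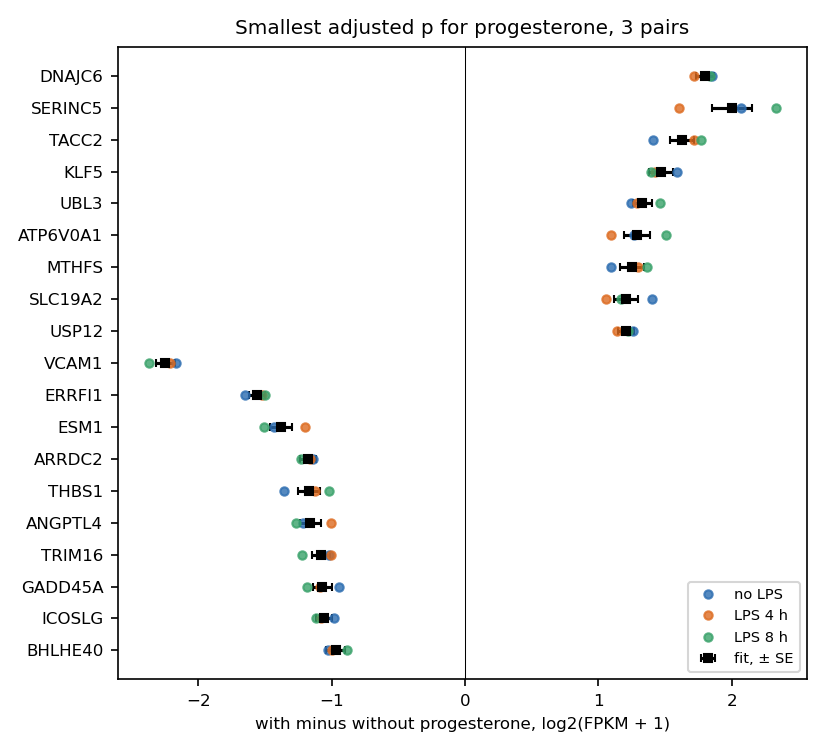
Difference with progesterone in log2(FPKM + 1) for genes of smallest adjusted p in each direction, with 1 coloured point per pair and the limma estimate as a black square with its SE. The pairs of VCAM1 lay at -2.17, -2.21 and -2.37, and the fitted difference of DNAJC6 was 1.8. VCAM1 stood at 0.6 FPKM in PR + P, below the added constant, so how close its pairs lay depends on that constant.

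Of 7759 genes, 614 rose and 441 fell (limma, Benjamini-Hochberg), 61 and 33 of them by at least 2-fold, and 2679 had an unadjusted p under 0.05. Differences correlated across genes between pairs that share no library, with Pearson r of 0.55 between no LPS and 4 h, 0.61 between no LPS and 8 h, and 0.67 between the LPS pairs over 7456, 9476 and 7451 genes, though genes are not independent replicates. This agreement also depends on the gene value. Over 7738 genes, r between the pairs without LPS and at 8 h was 0.49 with the length-weighted value, 0.02 with the planned sum and 0.01 with the most abundant transcript, and over the 593 genes with 1 transcript in each library 0.57, 0.31 and 0.31. Of the 22 genes at least 2-fold lower both without LPS and at 8 h, 0.9 were expected by chance, and 57 were higher in both with 2.1 expected. The libraries with progesterone also had more single-exon transcripts (52.4% to 52.7%, against 49.7% to 50.9% without) and shorter median transcripts (591, 569 and 602 bases, against 636, 611 and 611).

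The count for progesterone across 3 backgrounds rests on how a gene's value was formed. The planned value, the sum of FPKM over a gene's transcripts, gave 0 of 7802 genes in limma (489 at an unadjusted p under 0.05), and the most abundant transcript gave 0 (443 unadjusted). BHLHE40 changed sign under both of these values, and SLC19A2 with the sum. The length-weighted value was set after the files were seen, and before any limma result. Of 7738 genes compared, 7044 were assembled in different numbers of transcripts across libraries, and there the median residual SD was 0.744 for the sum and 0.107 for the length-weighted value. Where all 6 libraries held 1 transcript, the number of transcripts was equal, though the assembled length could still differ. There 13 of 593 genes passed with the sum (4 rose and 9 fell) and 81 with the length-weighted value (36 rose and 45 fell). Only transcripts with at least 50% of their length in the gene model were counted, and others could still enter the length-weighted value. In the 694 genes with equal transcript numbers the sum gave 0, and the length-weighted value had 46 rise and 62 fall, so the excess of rising genes over all genes was not seen in either set. In the progesterone across 3 backgrounds fit, leaving out the pair without LPS, at 4 h or at 8 h gave 603, 125 and 177 genes.

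Of 19 cytokines and chemokines tested, 7 fell (CXCL8, CXCL6, CCL2, CCL5, CXCL11, CSF1 and TNFSF10) and none rose, and adjusted over the list alone 10 fell and 1 rose. CXCL6 fell by 1.54 (SE 0.14), CCL2 by 1.33 (SE 0.22) and CXCL8 by 0.88 (SE 0.1), whereas CXCL1 had a log2 value of -0.42 (SE 0.36, limma adjusted p = 0.46) and ICAM1 of 0.4 (SE 0.11, limma adjusted p = 0.082). The pairs of CXCL1 lay at -1.51 without LPS, 0.09 at 4 h and 0.16 at 8 h, and its SE holds that difference between backgrounds. CCL20, CXCL10, CSF2, CSF3 and CX3CL1 were listed at 0 in both libraries without LPS. Their difference in that pair was therefore fixed at 0, and they were not among the 7. Without the 4 h pair 0 members of this list fell, without the 8 h pair 3, and without the pair free of LPS 13. Of 12 adhesion molecules SELE, VCAM1, ICAM2 and F11R fell, 5 fell and 1 rose adjusted over the list alone, and 1 fell without the 4 h or the 8 h pair. SELE, CXCL6 and CCL5 were listed at 0 in PR + P, so their fitted sizes depend on the added constant. Of 15 NF-kB feedback genes NFKBIB rose and IRAK2 and CFLAR fell (1 and 3 adjusted over the list alone), and without the 8 h pair none did. Of 10 TLR4 pathway components the ligase gene TRAF6 rose and the adaptor MYD88 fell (2 and 1 adjusted over the list alone). Of 18 interferon-stimulated genes 2 fell, MX1 among them (7 adjusted over the list alone), and none passed among 6 antigen presentation genes on either count. MYD88 passed in 0 of the 3 fits that left out 1 pair, TRAF6 did not pass without the 8 h pair, and 0 and 1 interferon-stimulated genes fell without the 4 h and the 8 h pair.

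Of 10 steroid receptor response genes ERRFI1, ANGPTL4 and GADD45A fell and none rose, with 5 lower adjusted over the list alone. Without the pair free of LPS, at 4 h or at 8 h, 3, 4 and 3 of them fell. Among 13 endothelial identity genes 5 fell, including the cadherin gene CDH5 (-0.55, SE 0.06), the VEGF receptor gene KDR (-0.41, SE 0.06) and ROBO4 (-0.62, SE 0.07), with 6 adjusted over the list alone. CDH5, JUP and CLDN11 fell among 11 junction genes (3 adjusted over the list alone). KLF2 (-1.39) and KLF6 (-0.74) fell among 6 immediate early genes (2 lower and 1 higher adjusted over the list alone). THBS1, PLAU and TFPI fell among 8 coagulation genes (4 adjusted over the list alone) and ADM and HMOX1 among 7 vasoactive genes (2 adjusted over the list alone). Of 11 matrix protease genes ADAM17, a sheddase, rose and MMP10, ADAMTS1, ADAMTS4 and CTSS fell, and the same numbers passed adjusted over the list alone. Of 14 cholesterol synthesis genes SC5D, DHCR7 and STARD4 rose and 3 fell, FDPS and LSS among them (5 and 3 adjusted over the list alone). DLL4, JAG2 and HES1 fell among 4 Notch pathway genes (3 adjusted over the list alone). None passed on either count among 20 cell cycle genes and 10 unfolded protein response genes. Most of these counts were smaller with 1 pair left out. Without the pair free of LPS, at 4 h and at 8 h, those that fell were 1, 0 and 0 junction genes, 3, 1 and 1 identity genes, 1, 1 and 1 coagulation genes, 1, 1 and 0 vasoactive genes, and 0, 1 and 0 Notch genes. In the same order 2, 0 and 2 immediate early genes and 3, 2 and 2 matrix protease genes fell, and for cholesterol synthesis 2, 1 and 0 genes rose and as many fell. ADAM17 did not pass without the 4 h pair. Of genes beyond the end of the 4 h file, SGK1 (-0.94, SE 0.11) and TNFAIP3 (-1.05, SE 0.1) fell and MAP3K7 rose (1.32, SE 0.13) in the limma fit over the pairs without LPS and at 8 h, each with an adjusted p of 0.0495. In that fit FKBP5 (-0.62) had a limma adjusted p of 0.0543 and IL6 (-0.71) of 0.0737.

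**Figure D4:**
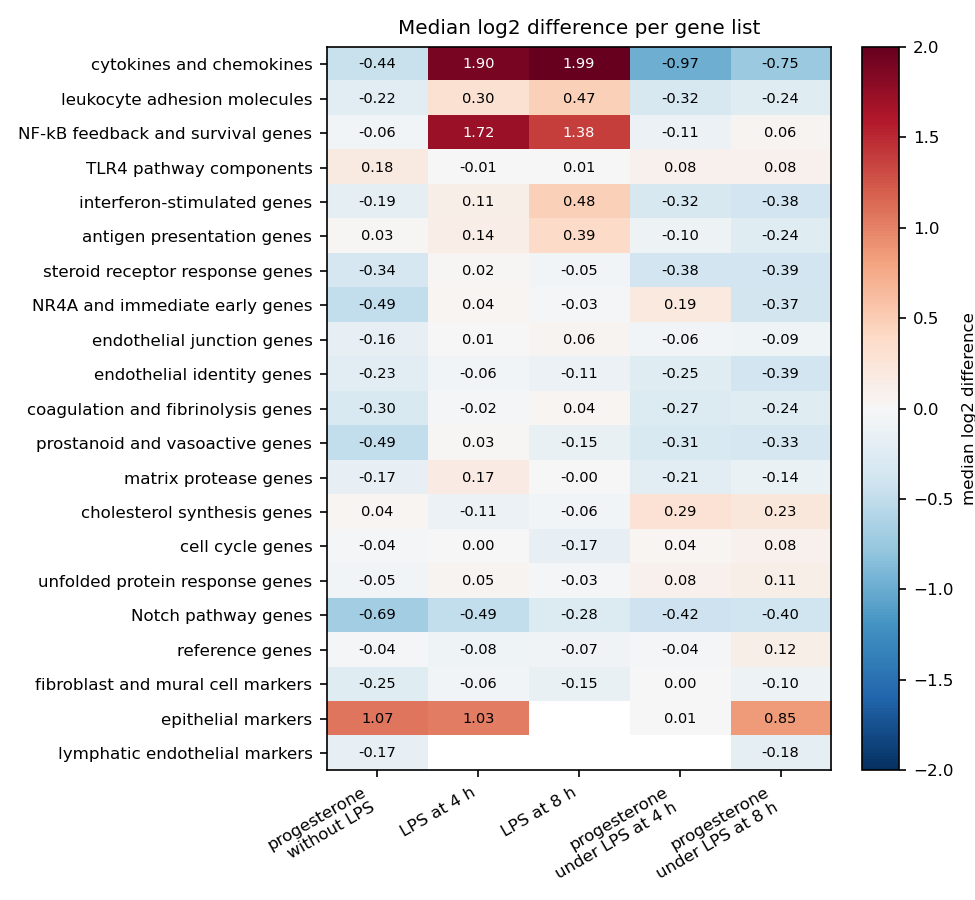
Median log2 difference of each gene list (rows) in 5 comparisons of 2 libraries (columns), with the value printed in each cell and the colour scale running from -2 to 2. Cytokines and chemokines were at 1.9 and 1.99 with LPS and at -0.97 and -0.75 with progesterone under LPS.

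Genes induced by LPS were then followed under progesterone, with genes chosen at one time and measured at the other so that no library served both steps. Of 36 genes at least 4-fold higher at 4 h of LPS than in PR, 23 were lower with progesterone at 8 h, with a median log2 difference of -0.26 (95% order-statistic interval -0.87 to 0.13). Of 32 genes chosen at 8 h, 23 were lower with progesterone at 4 h, with a median of -0.76 (-1.13 to -0.16). Both medians lay at percentile 0.0 of 10000 random lists matched on expression, whose central 95% ran from -0.09 to 0.15 at 8 h and from -0.09 to 0.1 at 4 h. VCAM1 (-2.37), CXCL10 (-2.28) and CCL20 (-1.84) were lowest at 8 h, while the heparan sulfate proteoglycan gene SDC4 (1.69) and ELOVL7 (1.15) were higher. These medians also rest on the gene value. For progesterone on LPS-induced genes at 8 h and progesterone on LPS-induced genes at 4 h, with the sum they were 0.1 at 8 h and 0.1 at 4 h, over 725 and 624 genes that passed the same 4-fold threshold.

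The 6 libraries were also read for markers of other cells. Progesterone raised ACTA2, an actin of smooth muscle, by 1.36 (SE 0.17) among 5 fibroblast and mural cell markers, and the list's median was -0.25 without LPS. PROX1, a transcription factor of lymphatic endothelium, rose by 1.7 (SE 0.22) and LYVE1, a hyaluronan receptor of the same cells, fell by 0.5 (SE 0.11), each in the limma fit. PROX1 stood at 0.45 FPKM in PR and at 0.33 and 0.25 FPKM at 4 h and 8 h of LPS alone. These lie below the added constant, so its fitted size and SE depend on that constant. LYVE1 passed in 0 of the 3 fits that left out 1 pair, and PROX1 did not pass without the 4 h pair. Of 3 epithelial markers none passed over all genes, and 2 rose and 1 fell adjusted over the list alone, with KRT8 at 2.98 and 19.6 FPKM and MUC1 at 0.561 and 2.28 FPKM without LPS. CD68 was the only leukocyte marker measured, at 4.55 FPKM in PR and 6.36 in PR + P, and did not pass. Of 5 reference genes POLR2A rose with progesterone by 0.35 (SE 0.06) and none passed with LPS. POLR2A passed in 0 of the 3 fits that left out 1 pair. GAPDH stood at 1331 FPKM in PR and 1271 at 4 h of LPS. YWHAZ, a reference gene beyond the end of the 4 h file, stood at 35.0 FPKM in PR, 59.9 in PR + P and 70.2 at 8 h of LPS. In the pair at 8 h of LPS against PR, 2 of 11 reference genes were higher and 9 lower, all within 2-fold.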

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

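The tests on exposure to LPS, the split of its induced genes and the correction for the share assembled were chosen only after the results were seen, and related values were known before some others. Differences between backgrounds below come from 1 library pair each and were not tested.

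The genes picked by size of difference in any comparison or from the gene lists were searched for a difference with progesterone that pointed opposite ways in 2 backgrounds, was at least 2-fold in either, and had Cufflinks intervals apart in both pairs. This gave 8 genes. Others switched direction without meeting all of these criteria, such as ATF3 (-0.38 without LPS, 1.88 at 4 h and 0.88 at 8 h), XBP1 (-0.07, 1.25 and 0.3) and TNFAIP2 (0.52, -0.4 and -0.43). CXCL1 was lower with progesterone without LPS (-1.51 in log2) and close to its partner at 4 h (0.09) and 8 h (0.16), a gap of 1.6 and 1.67. FOS stood at -0.34 without LPS and 1.72 at 4 h, a gap of 2.06, and TFPI2 at -0.24 and 1.04 at 8 h, a gap of 1.27. TOR1B went from 2.26 without LPS to -0.82 at 8 h, a gap of -3.09. The rest of the 8 were RAMAC (-1.76 and 0.86 at 8 h, gap 2.62), TCAF2 (-1.84 and 0.13 at 8 h, gap 1.97), AHNAK2 (-0.52 and 1.28 at 8 h, gap 1.8) and RPL29 (-0.22 and 1.23 at 4 h, gap 1.45). The cause was not tested.

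The first pattern weighed is the number of genes that passed for progesterone over the 3 pairs, 1055. After each library's trend with gene length was removed, 91.6% of them still passed with the same sign, and after its trend with GC content 87.6%, which argues against either trend as the whole cause. Across genes the difference with progesterone correlated with length at r = 0.05 and with GC content at r = -0.13. Dividing each value by the share of its gene model assembled kept 79.4% of the 1024 that could be corrected, which argues against less complete assembly with progesterone as the whole cause. That division moved the fitted difference by a median of 0.027 in log2 over 7417 genes. It stands in for a planned refit over 3885 well assembled genes, where 100.0% of the 629 that had passed did so again, as their choice had fixed. Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes, the real one, with 3 in the highest other. Of the 4 that part all 3 pairs the highest other gave 0, and the rest part 1 pair. These are too few splits for a share under 0.05. In each other split, a difference shared by the libraries with progesterone counts at least in part as spread, whatever its source. Low counts there would follow from any such difference and do not tell its source. How the gene value was formed and a technical difference shared by the libraries with progesterone stay open, as does progesterone itself.

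The second pattern is that LPS-induced genes were lower with progesterone under LPS. Weaker exposure to LPS in those libraries stays open. VCAM1, CCL2 and CXCL8, 3 of 3 genes looked at for this, were at least 2-fold lower with progesterone without LPS as well, but they were chosen once those values were known, so this decides nothing, and ICAM1 (0.54), TNFAIP2 (0.52), GCH1 (0.46) and NFKB2 (0.4) were higher there. Induced genes in the cytokine and adhesion lists had medians of -0.98 at 8 h (interval -1.84 to -0.26, 12 of 14 lower) and -1.17 at 4 h (-1.69 to -0.97, 13 of 15 lower), and those outside them 0.04 at 8 h (-0.33 to 0.45, 11 of 22 lower) and -0.21 at 4 h (-0.4 to 0.1, 10 of 17 lower). Induced genes assembled as 1 transcript in both libraries had a median of -0.99 at 8 h (interval -1.77 to 0.13) and -1.17 at 4 h (-1.69 to 0.09), so an effect of fragmented assembly on the gene value cannot be told apart with these few genes.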

How the results depend on the processing

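The length-weighted gene value, the assembly filter and the mask of fused transcripts were set after the data were seen, in place of the planned sum over transcripts. The alternatives to the filter and the mask, and assembly in all 6 libraries, were chosen only after the data were seen.

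The gene value decides most results. The fit for progesterone across 3 backgrounds passed 1055 genes with the length-weighted value and 0 with the sum over transcripts, the most abundant transcript or the analysis as first planned (489, 443 and 517 genes at an unadjusted p under 0.05 in limma). LPS at 4 h, with and without progesterone, gave 0 under the same 3 values (497, 429 and 521 unadjusted), as did LPS at 8 h, with and without progesterone (427, 368 and 442 unadjusted). Where the number of transcripts differed between libraries, the median residual SD was 0.744 for the sum and 0.107 for the length-weighted value. The medians for progesterone on LPS-induced genes at 8 h turned from -0.26 to 0.1, 0.1 and 0.11 with the most abundant transcript, the sum and the plan, and for progesterone on LPS-induced genes at 4 h from -0.76 to 0.07, 0.1 and 0.09. These rest on 692, 725 and 788 genes at 8 h and 605, 624 and 684 at 4 h, against 36 and 32.

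Counts of genes at least 2-fold apart moved too. With the most abundant transcript, the sum and the plan, progesterone without LPS gave 3084, 3805 and 4197 genes, LPS at 4 h 2317, 2880 and 3184, LPS at 8 h 2826, 3520 and 3900, progesterone under LPS at 4 h 2462, 2973 and 3291, and progesterone under LPS at 8 h 2798, 3522 and 3965, against 212, 140, 175, 181 and 312. Without the assembly filter the 5 counts were 478, 328, 401, 378 and 603, and with a pseudocount of 0.1 they were 446, 275, 337, 329 and 577. Both admit more genes at low values. The counts stayed within 1.5 times under median-ratio rescaling, the 50% assembly filter, fused transcripts kept and no filter beyond FPKM above 0.

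Single genes and lists counted as changing sign did so under the most abundant transcript, the sum or the plan. In pairs of libraries only genes of rank or fixed in advance were checked, and only differences of at least 2-fold were counted. A list was counted only where its median lay outside the range of random lists. In the fits the genes of smallest adjusted p were checked. For progesterone without LPS, the most abundant transcript put GFPT2 at -1.35, HMGB1 at -0.26 and SERINC5 at -0.28. The value of PBLD, progesterone without LPS, was -4.52 with it and -3.84 with the sum and the plan. There the sum and the plan both put GFPT2 at -1.7, SERINC5 at -0.83, TNFRSF10A at -0.28 and VCAM1 at 1.09. For LPS at 4 h, MRPS18C stood at 0.86 with the most abundant transcript and 0.87 with the others. For LPS at 8 h, AQP1 stood at 2.68 with each, and SNHG5 at 4.34 and then 4.16. For progesterone under LPS at 8 h, AKTIP stood at 1.03 and then 0.73, GON4L at 4.03 and then 3.06, KLF2 at 0.27 with the most abundant transcript, and GFPT2 at -0.08 with the sum and the plan.

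List medians for progesterone without LPS turned to 0.11 for vasoactive genes with the most abundant transcript and to 0.22 for interferon-stimulated genes with the sum. At 4 h of LPS alone the interferon list stood at -0.13 with the most abundant transcript. With progesterone at 4 h of LPS, vasoactive genes stood at 0.07 with the most abundant transcript, and with the sum and the plan the steroid response list stood at 0.02 and the Notch list at 0.45. At 8 h the antigen presentation list stood at 0.11 with the most abundant transcript and the sum and at 0.04 with the plan, the immediate early list at 0.04 with the most abundant transcript, and the Notch list at 0.19 with it and 1.22 with the sum and the plan. In the fits BHLHE40 turned to 1.66 with each, SLC19A2 to -0.24 with the sum and the plan, PRICKLE1 to 0.62 and then 1.87, RND1 at 8 h to -0.25 and then -0.49, and TBC1D8 to 1.0 with the most abundant transcript. The cause was not tested gene by gene.

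With leave-one-out, progesterone across 3 backgrounds gave 125 to 603 genes (1055 with all pairs). The fit for LPS at 8 h gave 32 without the 4 h pair, of which 21 were shared. These fits have fewer libraries, and without the 4 h pair they hold 9519 genes. A fit without a trend in the prior variance left the 3 counts within 1.5 times, as did assembly in all 6 libraries, while BMP4 had an adjusted p of 0.071 and CALCRL of 0.058 without the trend. Among single genes and lists, 252 of 310 kept their result with a pseudocount of 0.1, 289 with median-ratio rescaling, 307 without the assembly filter, and 305 with fused transcripts kept. Far fewer did so with another gene value, 82 with the most abundant transcript (124 moved, 20 reversed and 77 were weaker), 86 with the sum (120, 20 and 77) and 88 with the plan (119, 19 and 77). In the fits, where weaker means an adjusted p of 0.05 or more for a gene or a gene count more than 1.5 times lower for a list, 30 kept their result without the pair free of LPS (8 weaker and 3 stronger), 31 without the 4 h pair (22 weaker) and 37 without the 8 h pair (19 weaker). Without the trend in the prior variance 71 kept their result and 10 were weaker, BMP4 and CALCRL among them. The medians of LPS-induced genes kept their sign when genes were at least 2-fold induced. They also did when genes were chosen at the same time, but there the library with LPS alone served both choice and measurement. That by itself favours lower values with progesterone, so the same-time choice decides nothing.

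Depth was close between libraries, 33480977 to 40377788 fragments, and limits mainly genes of few fragments, such as NR4A1, whose ratio at 4 h had a 95% interval from 0.817 to 3.49. Genes not assembled are listed at 0 whatever their depth.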

Other observations

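All observations here were made after the data were seen. With at least 25% of the model taken as assembled, 18 genes were assembled in every LPS library that covers them and in neither library without LPS, with FPKM of at least 1 in at least 1 LPS library. CCL20, CSF2, CSF3, CX3CL1, CXCL10, LTB and TNFRSF4 were among them. Another 9 were assembled only in both libraries without LPS, with FPKM of at least 1 in at least 1 of them, among them COL1A1, MAP3K7CL and SULT1A1. LTB, a member of the tumour necrosis factor family, stood at 6.91, 6.18 and 5.65 FPKM in the 3 LPS libraries that cover it.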
